A study of Mus musculus with 6 samples.

How the data were processed

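RNA was sequenced from epididymal white adipose tissue (eWAT), the fat pad next to the epididymis of male mice. The 6 samples were 3 mice labelled Jmjd8-KO and 3 wild-type mice (WT), all C57BL/6 and fed a high-fat diet (HFD), which enlarges this depot and draws macrophages into it. Per the labels' protocols, the tissue was flash frozen, RNA was taken with Trizol and a column kit, and libraries made with a BGI kit were sequenced on a BGISEQ machine. The knockout allele, length of the diet, age, litter, date of collection, read length and strand of the library are not given in the sources used here.

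The authors deposited 1 table of 24539 genes that gives, for every mouse, a raw count and an RPKM value (reads per kilobase of gene, scaled to library size). Per the submitters' processing notes, reads were aligned with STAR to mm10 and the counts made with featureCounts. Tool versions, the gene annotation, the treatment of reads that fall on several genes or places, and the strand setting are not given in the sources used here. Per the file headers the count columns are unnormalized, and they hold whole numbers that sum to different totals. The deposited RPKM columns were used for 1 check and not tested: over 8884 genes with at least 200 counts in every library, the count divided by the RPKM stood in a fixed ratio between libraries. Relative to Jmjd8-KO replicate 1, the library size this implies differed from the total count by between -0.81% and 0.41%, so the authors' library sizes were not exactly the column totals. No row named anything but a gene, no gene was listed more than once, and no mitochondrially encoded gene was listed. Gene positions are those of GENCODE release M21 on GRCm38, the same assembly as mm10, matched by symbol for 97.3% of genes.

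Total counts lay between 17598696 and 20598473 per library. Counting error is therefore small for the genes described, except those near 1 CPM (the count scaled to library size), and the spread between mice sets the precision. Each sample is a separate mouse per the series' design text. Jmjd8-KO replicates 1 and 3 were the most similar pair, with a chi-square of 3.19 per degree of freedom over genes, against 1 for counting noise alone. WT replicates 2 and 3 gave 4.38, and the other pairs within a group gave 23.7 to 51.1, so all 6 were counted as separate samples.

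The comparison was Jmjd8-KO against WT, with 3 mice in each group and genotype as the only term. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 14322 genes. Counts were scaled by TMM factors and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3). p-values were adjusted by Benjamini and Hochberg over the tested genes, and a gene passed at an adjusted p under 0.05. Log2 fold changes are Jmjd8-KO minus WT. Their standard error (SE) is the size of the log2 fold change over the square root of the F statistic, and means are CPM ± SD over 3 mice. Any p below, unless said otherwise, is an adjusted p from this test.

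The 40 gene lists were fixed before the data were examined. The 36 of them with at least 5 measured members, leaving out the sex check genes and the genes next to Jmjd8, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. Camera asks whether a list ranks higher or lower than the other genes. It used a preset correlation between genes of 0.01, and was repeated with a correlation estimated for each list. Fry, from the same package, asks whether the genes of a list move on balance one way. Within a list, members were counted after adjustment over all genes and also adjusted over the list alone. Some genes are members of more than 1 list, among them 7 of 19 in the adipocyte identity list and 6 of 15 in the lipolysis list.

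Genes to name were chosen by a rule fixed before the data were examined. Jmjd8 came first. Next came the 8 genes that rose most and the 8 that fell most among those that passed, with a mean of at least 1 CPM in a group and no overlap between the groups, leaving out names of gene models. A set of lists on inflammation, macrophages, adipocytes, insulin, lipids and the endoplasmic reticulum (ER) was named in advance, and each of these passed. From each list came the members with the smallest p: 4 where the list passed, 3 where one of that set did not, and 1 otherwise. The text takes its examples from these, leaving out some that are not reported here, and says so where a gene was picked after its values were seen.

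The test was tried on simulated counts drawn from the means, dispersions and library sizes of these samples. The genes to change were drawn from those with a mean of at least 1 CPM, so the shares recovered do not cover genes below that level. No simulated library differed from its group over many genes at once, as real ones did. Over 14322 simulated genes, edgeR recovered 22.4% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 93.9% of those changed 4-fold. In that run 10.3% of the genes called had not been changed, and 3 genes were called when none had been. Camera called 5 of 5 simulated lists shifted by 0.5 on the log2 scale and no list in 10 draws without a shift; these counts were drawn gene by gene and hold no correlation between genes, so they do not test camera's preset correlation.

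Alternatives fixed in advance were other scalings (RLE, upper quartile, library size alone), other tools (DESeq2 1.42.0, limma-voom with and without quality weights), other filters, a minimum fold change (glmTreat), the replicate number as a block, and leaving out each mouse in turn. Chosen after seeing the data were a fit without both libraries that stand apart, an offset for GC content and gene length with and without the block, and edgeR's robust fit. Gene length for the offset was the count over the RPKM, and GC content came from the GENCODE transcripts. Lists of markers for neurons, oligodendrocytes, astrocytes, choroid plexus, microglia, peripheral nerve, liver, kidney and heart were written after WT replicate 1 was seen to stand apart, and a list of imprinted genes after 3 of them were seen to rise.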

Results

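The data are gene counts from epididymal fat of 6 mice on a high-fat diet, 3 labelled Jmjd8-KO and 3 wild-type. Jmjd8 encodes a protein of the JmjC-domain family reported in the lumen of the ER. The design asks which genes of this fat depot are expressed differently between these genotypes. Total counts were 19414341, 20598473 and 17598696 in Jmjd8-KO replicates 1, 2 and 3, and 19510625, 19477779 and 19387267 in WT replicates 1, 2 and 3. Scd1, a fatty acid desaturase abundant in adipocytes, took the most counts in every library, 6.21% to 9.17% of the total.

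A library in each group stood apart from the other members of its group. WT replicate 1 carried transcripts of the nervous system. Snap25, a protein of the synapse, had 2511 counts there against 20 and 11 in WT replicates 2 and 3, and Camk2a, a kinase of neurons, had 7068 against 122 and 154, both named after their values were seen. The median count over all listed genes was 78 in this library and 42 to 50 in the other 5. Jmjd8-KO replicate 2 differed from Jmjd8-KO replicates 1 and 3 over many genes at once, with a chi-square of 51.1 and 47.8 per degree of freedom against 3.19 between those 2. Counts with each of these libraries left out are given with the groups described.

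**Figure D1:**
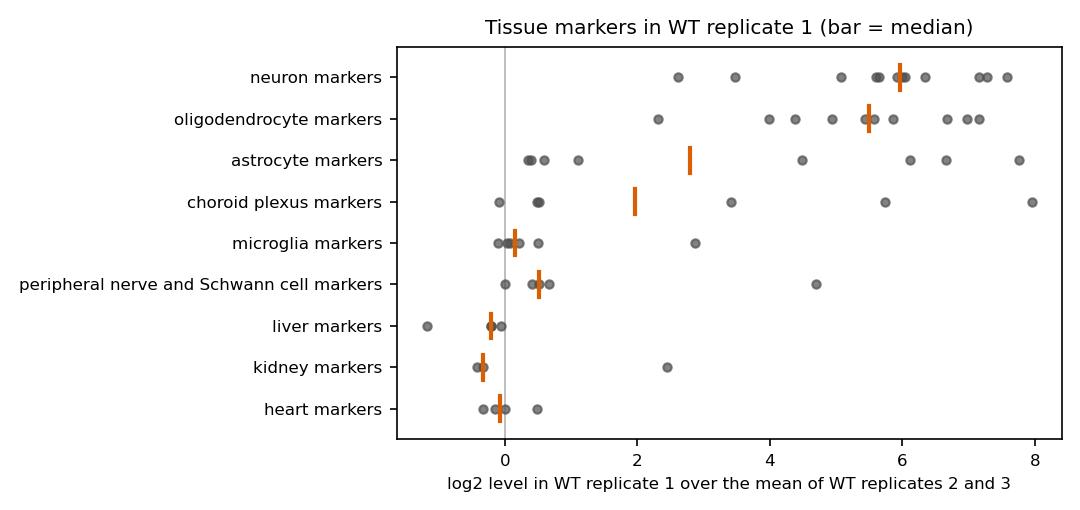
Log2 level of tissue markers in WT replicate 1 over the mean of WT replicates 2 and 3, by list. Each point is a gene with at least 10 counts over the 6 libraries and the bar is the median of the list. Neuron markers have a median of 5.96 and liver markers of -0.20.

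Jmjd8 itself fell in the knockout mice. Its counts were 748, 1147 and 728 in Jmjd8-KO and 2277, 2284 and 2209 in WT, or 46.5 ± 9.81 CPM against 113.2 ± 2.34 CPM (SD, n = 3 each). The log2 fold change was -1.28 (SE 0.144, adjusted p = 0.0193), so that the knockout libraries held 41.1% of the WT level, with the highest value in Jmjd8-KO replicate 2. The gene lies on the plus strand of chromosome 17 from 25828867 to 25831843 (GRCm38). Its end overlaps Stub1, a ubiquitin ligase gene on the minus strand from 25830505 to 25833404, and the microRNA gene Mir3082, which starts at 25831365. The knockout allele and the strand setting are not given in the sources used here, so the remaining counts cannot be assigned to exons of Jmjd8 or, in the overlap, to a gene. Mir3082, named after its value was seen, fell (log2 fold change -2.18, adjusted p = 0.0293; 0.0865 without WT replicate 1). Stub1 had a log2 fold change of -0.19 (SE 0.199, adjusted p = 0.616), with 106.6 CPM in Jmjd8-KO replicate 2 against 63.2 and 65.4 CPM in the other Jmjd8-KO mice, and fell without that library (-0.48, adjusted p = 0.00708). None of the 10 measured neighbours in the list of genes next to Jmjd8 passed, the smallest p being that of Rhbdl1, a rhomboid protease (log2 fold change 0.84, SE 0.282, adjusted p = 0.177). No neighbour passed without WT replicate 1, and without Jmjd8-KO replicate 2 Stub1 fell and Rhbdl1 rose (0.41, adjusted p = 0.0275). The call for Jmjd8 was lost when any mouse but Jmjd8-KO replicate 2 was left out (adjusted p from 0.058 without WT replicate 1 to 0.137 without WT replicate 3), and without Jmjd8-KO replicate 2 the adjusted p was 0.00101.

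Between the groups, lists of pan-macrophage and obesity-linked macrophage markers, cytokines and cell cycle genes ranked lower in Jmjd8-KO fat, and lists of adipocyte, mesothelial and resident macrophage genes ranked higher. These list calls used a preset correlation between genes of 0.01, and with a correlation estimated for each list 0 of 36 lists passed. Among these 7 lists the estimate ran from -0.0195 for cytokines, under the preset, to 0.26 for mesothelial markers. The loss of the cytokine call therefore cannot be laid to a larger correlation. Without WT replicate 1 no member of these 7 lists passed on its own, in a fit where 17 genes passed in all. All 7 kept their list call there with the preset correlation. Of 14322 genes tested, 304 passed, 113 higher and 191 lower in Jmjd8-KO. At an unadjusted p under 0.05 there were 2735. Among the 304, 16 rose and 64 fell by at least 2-fold, and in all 304 the 3 values of one group lay outside those of the other. The groups did not overlap in 29.5% of tested genes, where chance gives 10%. Of the called genes 62.8% were lower, a share that depended on the setting. It was 77.4% of 372 when counts were scaled by library size alone. With DESeq2 it was 51.6% of 1039, and by limma-voom with quality weights 50.8% of 2030. The share was 88.2% of 17 without WT replicate 1, 51.6% of 1351 without Jmjd8-KO replicate 2 and 49% of 2833 without both.

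The 8 largest rises were in genes of various functions. Cyp2e1, a cytochrome P450 of ethanol and fatty acid oxidation, was at 437.8 ± 56.3 CPM in Jmjd8-KO and 106.5 ± 10.3 CPM in WT (4.11-fold, log2 fold change 2.04, SE 0.122). Angptl7, a secreted angiopoietin-like protein, rose from 1.05 ± 0.192 to 6.96 ± 3.57 CPM (log2 fold change 2.72, SE 0.429), with values of 3.43 to 10.6 between the Jmjd8-KO mice. Pck1, the gluconeogenic and glyceroneogenic enzyme that supplies glycerol for triglycerides in fat, rose 2.35-fold to 1027 ± 238 CPM. Alox15, a lipoxygenase, rose 2.81-fold, the heat shock proteins Hspa1a and Hspa1b 2.66- and 2.51-fold, and the keratin Krt8 2.36-fold. Ripk4, a kinase of epithelial cells, rose from 0.318 ± 0.0618 to 1.22 ± 0.339 CPM. Adjusted p for these 8 genes lay between 0.00288 and 0.0421. Cyp2e1 passed without WT replicate 1 (adjusted p = 0.0101) and the other 7 did not, with adjusted p from 0.0828 for Alox15 to 0.137 for Ripk4.

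The largest falls were in genes of low or moderate level. Gpr50, an orphan receptor related to the melatonin receptors, fell from 76.3 ± 13.3 to 3.1 ± 0.991 CPM (log2 fold change -4.63, SE 0.257, adjusted p = 0.00288), and its log2 fold change was -4.55 without WT replicate 1. Cck, the peptide hormone cholecystokinin, fell from 16.4 ± 11.5 to 0.406 ± 0.1 CPM (log2 fold change -5.30). Cck is also a gene of the brain, and WT replicate 1 held 29.7 CPM against 8.92 and 10.5 CPM in the other WT mice; without it the log2 fold change was -4.56 (adjusted p = 0.00562). Pcp4l1, likewise highest in WT replicate 1 at 10.2 CPM, had a log2 fold change of -2.54 with it and -2.14 without it. Akr1b7, an aldo-keto reductase, Themis, a protein of T cell development, Sptlc3, a subunit of serine palmitoyltransferase, Ereg, the growth factor epiregulin, and Hpx, the haem-binding hemopexin, fell with log2 fold changes of -4.77, -3.15, -2.92, -2.62 and -2.54, all at 3.57 CPM or less in WT. Gpr50, Cck and Akr1b7 passed without WT replicate 1, while Themis, Hpx and Pcp4l1 (adjusted p = 0.0504 each) and Sptlc3 and Ereg (0.0943 and 0.0944) did not.

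How many genes passed depended on single mice. The count was 17 without WT replicate 1, 1351 without Jmjd8-KO replicate 2, and 2833 without both, a choice that leaves the most similar pair of each group and so lowers the spread. It was 3 without Jmjd8-KO replicate 1, 4 without Jmjd8-KO replicate 3, 4 without WT replicate 2 and 0 without WT replicate 3, where edgeR gave 2119 genes at an unadjusted p under 0.05. None of the 304 changed sign in any of these fits, which is no test of stability. The groups do not overlap in any of the 304, so leaving out mice could hardly reverse a sign.

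**Figure D2:**
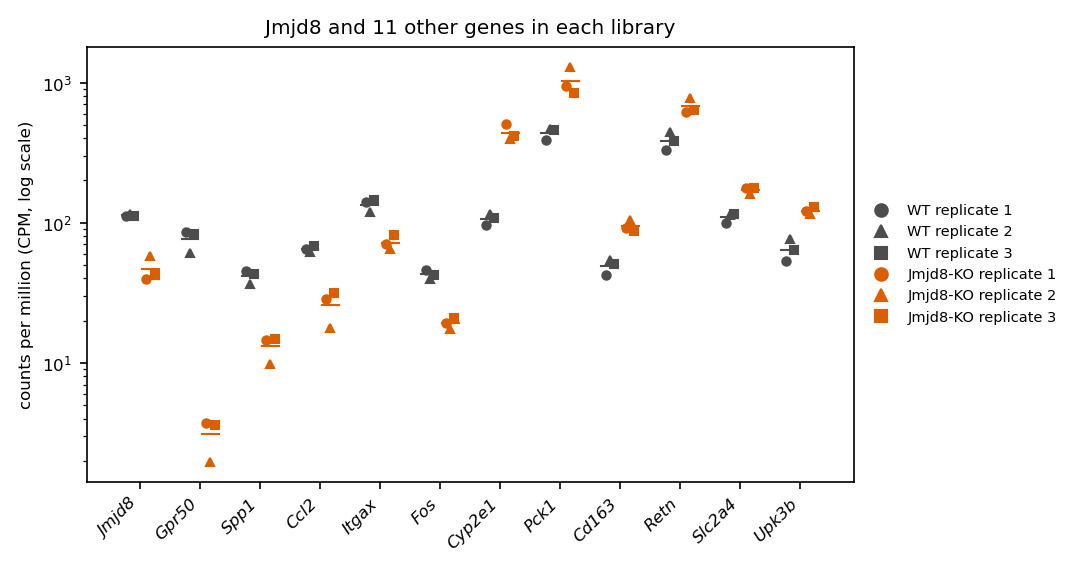
Level of Jmjd8 and 11 other genes in each library, in CPM on a log scale. Points are mice, marked by replicate number, grey for WT and orange for Jmjd8-KO, and lines are group means of 3 mice. Gpr50 lay between 61.05 and 85.6 CPM in WT and between 1.96 and 3.74 CPM in Jmjd8-KO.

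Some macrophage markers fell and others did not pass. Of 16 measured pan-macrophage markers, 7 fell, 0 rose and 9 did not pass (median log2 fold change -0.53), and 11 fell when adjusted over the list alone. Tyrobp, a signalling adaptor, went from 154.9 ± 5.87 to 90.9 ± 6.70 CPM (log2 fold change -0.77, SE 0.0798), Fcgr1, an antibody receptor, had a log2 fold change of -0.93 (SE 0.126), the lysosomal protease Ctss of -0.63 (SE 0.0781) and the complement protein C1qb of -0.61 (SE 0.0888). Csf1r, the receptor on which macrophages depend, was at 397.8 CPM in Jmjd8-KO and 404.5 CPM in WT (log2 fold change -0.02, SE 0.0753), and is named after its value was seen. Of 12 markers of lipid-associated macrophages, the kind that gathers in obese fat, 5 fell and 0 rose (median -0.80; 9 fell adjusted over the list alone). Spp1, the secreted protein osteopontin, fell 3.19-fold to 13.1 ± 2.81 CPM (log2 fold change -1.68, SE 0.176), Itgax, the integrin CD11c, fell 1.87-fold, Cd9, a tetraspanin, 1.64-fold and Lgals3, galectin-3, 1.61-fold, while Ctsd, a lysosomal protease, had -0.01 and Cd63, a tetraspanin, 0.13 (both named after their values were seen). Both lists passed (camera adjusted p = 1.07e-07 and 9.76e-07), and both calls were lost with an estimated correlation (adjusted p = 0.146 with an estimated correlation for each). Without Jmjd8-KO replicate 2, 13 and 10 members fell; without WT replicate 1, 0 members of either list passed, with medians of -0.54 and -0.74.

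Of the markers of resident macrophages, some rose and most did not pass. Of 10 measured, 3 rose, 0 fell and 7 did not pass (median 0.24), and 3 rose adjusted over the list alone. Cd163, a scavenger receptor for haemoglobin, rose from 48.9 ± 6.24 to 94.6 ± 9.27 CPM (log2 fold change 0.95, SE 0.119), Retnla, the secreted protein RELM alpha, from 151.8 ± 20.0 to 332.5 ± 91.0 CPM (1.13, SE 0.197), and F13a1, a subunit of coagulation factor XIII, from 213.6 ± 28.3 to 319.2 ± 5.88 CPM (0.58, SE 0.106). Cbr2, a carbonyl reductase, had a log2 fold change of 0.36 (adjusted p = 0.182). Of members named after their values were seen, Folr2, a folate receptor, had -0.33, Mrc1, the mannose receptor, -0.18, the lectin Clec10a 0.07, Timd4, a receptor for dying cells, 0.10 and Lyve1, a hyaluronan receptor, 0.17. The list passed (camera adjusted p = 0.0161; adjusted p = 0.272 with an estimated correlation). The list's call was also lost without Jmjd8-KO replicate 3. No member passed without WT replicate 1, where the median was 0.14, and 3 rose without Jmjd8-KO replicate 2.

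Some chemokines and other inflammatory genes fell. Of 22 cytokines, chemokines and NF-kB targets, 4 fell, 0 rose and 18 did not pass (median -0.64), and 12 fell adjusted over the list alone. Ccl2, the chemokine that recruits monocytes, fell from 64.8 ± 3.31 to 26.0 ± 7.32 CPM (log2 fold change -1.32, SE 0.201), Cxcl10 fell from 10.4 ± 0.748 to 4.45 ± 0.444 CPM (-1.22, SE 0.141), the acute-phase lipocalin Lcn2 had a log2 fold change of -1.15 (SE 0.185) and the chemokine Ccl7 of -0.72 (SE 0.134). The list passed (camera adjusted p = 1.07e-07; adjusted p = 0.0944 with an estimated correlation). Without WT replicate 1, 0 members passed (median -0.53), and without Jmjd8-KO replicate 2, 8 fell. Of 24 interferon-stimulated genes, 1 fell, Ifi27l2a (log2 fold change -0.59, SE 0.0883), with 1 adjusted over the list alone, while Zbp1, a sensor of nucleic acids, had -0.62 (adjusted p = 0.101) and the GTPase Gbp3 0.29 (adjusted p = 0.214). That list's median was -0.12 (camera adjusted p = 0.0306; adjusted p = 0.165 with an estimated correlation). The call for that list was also lost without Jmjd8-KO replicate 1, Jmjd8-KO replicate 2, WT replicate 2 or WT replicate 3. With the replicate number as a block it was lost too. Of 9 mast cell and eosinophil markers, 1 fell, the mast cell protease Mcpt4 (log2 fold change -0.84, SE 0.147), with 1 adjusted over the list alone. Tpsb2, Cma1 and Cpa3, also mast cell proteases, had -0.52, -0.54 and -0.86 without passing (median of the list -0.52, camera adjusted p = 0.0131; adjusted p = 0.165 with an estimated correlation). Without WT replicate 1, 0 members of either list passed, and without Jmjd8-KO replicate 2, 3 members of each fell.

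Other immune lists did not pass as wholes, though each held a gene that did. Il7r, the interleukin 7 receptor, was the 1 of 14 T and NK cell markers to fall (49.2 ± 5.18 to 24.65 ± 4.76 CPM; camera adjusted p = 0.128 for the list, which passed with the stricter filter). Jchain, the joining chain of secreted antibodies, was the 1 of 7 B and plasma cell markers to fall, from 60.3 ± 6.66 to 23.2 ± 4.25 CPM, where 2 fell adjusted over the list alone and the list had a camera adjusted p of 0.446, with a median of 0.15 but a mean of -0.28. H2-DMb1, a chaperone of peptide loading, fell by 0.50 on the log2 scale among 10 genes of MHC class II presentation, 7 of which had a positive log2 fold change (camera adjusted p = 0.575). Among 12 complement genes C2, a protease of the classical pathway, rose (0.45, SE 0.0792; named after its value was seen) and C5ar1, a receptor for complement C5a, fell (-0.77, SE 0.11), and 1 was higher and 2 lower over the list alone. The complement list had a median of 0.14 and a mean of -0.04 (camera adjusted p = 0.446). S100a8, an alarmin of neutrophils, fell from 13.8 ± 1.59 to 4.9 ± 0.149 CPM in a list too short to test, with 4 members measured, of which 2 were higher and 1 lower over the list alone. S100a8 passed without WT replicate 1 (adjusted p = 0.043), while Il7r (0.0865), Jchain (0.058), H2-DMb1 (0.101), C5ar1 (0.0905) and C2 (0.156) did not. Without Jmjd8-KO replicate 2, 1 T and NK cell, 1 B and plasma cell and 1 neutrophil marker fell, 1 MHC class II gene rose and 1 fell, and 1 complement gene rose and 2 fell. The median of the T and NK cell list was -0.30 and -0.15 without Jmjd8-KO replicate 2, and that of the complement list was 0.06 without WT replicate 1.

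Some adipocyte genes rose. Of 19 measured adipocyte identity genes, 4 rose, 0 fell and 15 did not pass (median 0.39), and adjusted over the list alone 13 rose and 1 fell. Retn, the hormone resistin, went from 383.6 ± 56.6 to 676.1 ± 83.5 CPM (log2 fold change 0.82, SE 0.136), Nnat, neuronatin, from 357.4 ± 9.21 to 582.7 ± 51.2 CPM (0.71, SE 0.0854), Acvr1c, the activin receptor ALK7, from 77.2 ± 6.99 to 122.8 ± 10.4 CPM (0.67, SE 0.0983) and Slc2a4, the insulin-responsive glucose transporter GLUT4, from 109.3 ± 8.07 to 171.8 ± 10.3 CPM (0.65, SE 0.086). The list passed (camera adjusted p = 7.09e-07; adjusted p = 0.165 with an estimated correlation). No member passed without WT replicate 1, where the median was 0.31, and 10 rose without Jmjd8-KO replicate 2. Of 17 genes of insulin signalling and glucose uptake, 3 rose and 0 fell, with 6 higher and 1 lower adjusted over the list alone. They were Slc2a4, Pde3b, the phosphodiesterase through which insulin restrains lipolysis (0.61, SE 0.0787), and Foxo1, a transcription factor that insulin inhibits (0.45, SE 0.0783), while Tbc1d4, which holds GLUT4 inside the cell, had 0.39 (adjusted p = 0.054). That list passed too (median 0.21, camera adjusted p = 5.15e-04; adjusted p = 0.165 with an estimated correlation), and 0 members passed without WT replicate 1 against 6 without Jmjd8-KO replicate 2.

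Lists of lipid synthesis, lipolysis and mitochondrial catabolism ranked higher in Jmjd8-KO by camera, with few or no members passing. Of 22 genes of fatty acid and triglyceride synthesis, 2 rose, Pck1 and Thrsp, a regulator of lipogenesis (377.3 ± 9.93 to 724.8 ± 134 CPM, log2 fold change 0.94, SE 0.131); adjusted over the list alone 10 were higher and 1 lower. Elovl6, a fatty acid elongase, had -0.84 (adjusted p = 0.0682) and Srebf1, a transcription factor of lipogenesis, 0.34 (adjusted p = 0.108). The median was 0.20, and 0.12 without WT replicate 1 (camera adjusted p = 8.06e-04; adjusted p = 0.272 with an estimated correlation). All 18 measured genes of branched-chain amino acid catabolism had a positive log2 fold change (median 0.27), of which 1 passed, Aldh6a1, a mitochondrial dehydrogenase of valine breakdown (0.51, SE 0.0817), and 9 passed adjusted over the list alone (camera adjusted p = 2.41e-06; adjusted p = 0.182 with an estimated correlation). Among 15 genes of lipolysis and lipid droplets none passed over all genes, and 5 were higher and 1 lower over the list alone. Lipe and Pnpla2, the hormone-sensitive and adipose triglyceride lipases, had 0.35 and 0.33, Plin4, a droplet coat protein, 0.39 and Plin2, another, -0.37 (camera adjusted p = 0.0161; adjusted p = 0.297 with an estimated correlation). None of 15 genes of the TCA cycle passed (median 0.13, camera adjusted p = 0.0251; adjusted p = 0.211 with an estimated correlation), nor did any of 29 subunits of oxidative phosphorylation (median 0.19, camera adjusted p = 0.0384; adjusted p = 0.598 with an estimated correlation). The mean of the oxidative phosphorylation list was 0.38 above the WT mean in Jmjd8-KO replicate 2 and 0.01 and 0.02 above it in the other Jmjd8-KO mice, and its median was 0.03 without that library. Without WT replicate 1 no member of these 5 lists passed, and without Jmjd8-KO replicate 2 there were 7 higher and 1 lower in lipid synthesis, 6 higher in branched-chain amino acid catabolism, 4 higher and 1 lower in lipolysis, 1 higher in the TCA cycle and 0 in oxidative phosphorylation. The calls for lipolysis, the TCA cycle and oxidative phosphorylation were lost without WT replicate 1, that for the TCA cycle also without Jmjd8-KO replicate 1 or 3, and that for oxidative phosphorylation also without Jmjd8-KO replicate 2 or WT replicate 3 and by fry (adjusted p = 0.411). The median of the lipolysis list was 0.28, and 0.14 without Jmjd8-KO replicate 2. The call for lipolysis was also lost with genes in more than 1 list left out, which takes 6 of its members, and with the GC and length offset. Both lipolysis and oxidative phosphorylation lost it without the 2 libraries that stand apart, and the TCA cycle and oxidative phosphorylation with library size alone.

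Fatty acid oxidation and thermogenic genes did not pass. Of 21 genes of fatty acid oxidation none passed over all genes and 1 was higher over the list alone (median 0.07, camera adjusted p = 0.109), the smallest p being that of Ehhadh, a peroxisomal enzyme (0.50, adjusted p = 0.0534). Of 14 thermogenic genes none passed over all genes and 3 were lower over the list alone, led by Elovl3, an elongase of brown fat (-1.75, adjusted p = 0.0662), and the list's median was -0.02 (camera adjusted p = 0.639; fry adjusted p = 0.0314). In neither list did a member pass without WT replicate 1, and without Jmjd8-KO replicate 2, 2 oxidation genes rose and 1 fell and 1 thermogenic gene rose and 2 fell, with medians of 0.04 and -0.03. The fatty acid oxidation list passed with genes in more than 1 list left out.

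ER chaperone genes, examined because the Jmjd8 protein is reported in the ER, had small log2 fold changes. None of 27 genes of the unfolded protein response passed, over all genes or adjusted over the list alone, and 19 had a positive log2 fold change (median 0.15, camera adjusted p = 0.0138; adjusted p = 0.423 with an estimated correlation). Asns, asparagine synthetase, had 0.40 (adjusted p = 0.0912), Hyou1 and Pdia4, ER chaperones, 0.29 and 0.25, and Herpud1, a factor of ER-associated degradation, 0.42. The call was lost by fry (adjusted p = 0.0788), without WT replicate 1 and without both libraries that stand apart. No member passed without WT replicate 1, and 3 rose without Jmjd8-KO replicate 2, where the median was 0.09. Of 25 other JmjC-domain genes none passed, the smallest p being that of Kdm5b, a histone demethylase (0.37, adjusted p = 0.133; camera adjusted p = 0.0784 and fry adjusted p = 0.0075 for the list), and the list passed by camera without Jmjd8-KO replicate 2 and with no filter on low counts.

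Some cell cycle genes and immediate early genes fell. All 19 measured cell cycle genes had a negative log2 fold change (median -0.53), 2 fell and 12 fell adjusted over the list alone. These 2 were Mcm5, a subunit of the replication helicase (20.3 ± 2.11 to 12.3 ± 0.35 CPM, -0.72, SE 0.109), and Rrm2, a subunit of ribonucleotide reductase (-0.88, SE 0.162), while Top2a, topoisomerase II alpha, had -0.36 and Tpx2, a spindle protein, -0.63 (camera adjusted p = 1.06e-10; adjusted p = 0.0944 with an estimated correlation). Of 16 immediate early genes, which respond within minutes to stimulation and to handling of tissue, 5 fell and 0 rose, and 10 fell adjusted over the list alone. Fos went from 42.7 ± 3.01 to 19.3 ± 1.77 CPM (-1.15, SE 0.103) and Fosb from 6.17 ± 0.286 to 1.83 ± 0.106 CPM (-1.75, SE 0.163), both subunits of AP-1, and the transcription factors Atf3 and Egr2 had -0.87 and -0.82 (median of the list -0.65, camera adjusted p = 2.41e-06; adjusted p = 0.0944 with an estimated correlation). Without WT replicate 1, 2 immediate early genes and 0 cell cycle genes fell, and without Jmjd8-KO replicate 2, 7 and 8 did.

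Lists of lysosomal and cholesterol synthesis genes ranked lower in Jmjd8-KO, and mesothelial markers ranked higher. Of 20 lysosomal genes 0 passed over all genes and 8 fell adjusted over the list alone. Gusb, a glycosidase, had -0.33, Atp6v1a, a subunit of the proton pump, -0.30 and Npc2, a cholesterol carrier, -0.27 (camera adjusted p = 1.05e-04; adjusted p = 0.137 with an estimated correlation). Of 18 genes in the cholesterol synthesis list 1 fell over all genes and 7 fell adjusted over the list alone, with Sqle, Dhcr7 and Msmo1, enzymes of sterol synthesis, at -0.41, -0.71 and -0.44 (median -0.30, camera adjusted p = 2.73e-05; adjusted p = 0.137 with an estimated correlation). Of 10 markers of mesothelium, the layer that covers the fat pad, 3 rose, 0 fell and 9 rose adjusted over the list alone (median 0.79). Upk3b, a uroplakin, went from 64.3 ± 11.7 to 121.5 ± 7.37 CPM (0.92, SE 0.136), Upk1b, another, had 0.68 (SE 0.114), Krt8 1.24 (SE 0.217) and Msln, mesothelin, 0.71 (adjusted p = 0.0623). The list passed (camera adjusted p = 1.07e-07; adjusted p = 0.146 with an estimated correlation). Without WT replicate 1, 0 members of these 3 lists passed, and without Jmjd8-KO replicate 2, 9 lysosomal and 7 cholesterol genes fell and 8 mesothelial genes rose.

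Markers of other cells of the fat pad, and several further groups, did not pass. None of 12 endothelial markers passed (median 0.07, camera adjusted p = 0.514; Vwf, von Willebrand factor, 0.45, adjusted p = 0.131), nor did any of 13 adipose progenitor and fibroblast markers (median -0.00436, camera adjusted p = 0.887; Ly6a, the stem cell antigen, -0.39, adjusted p = 0.2) or any of 24 genes of extracellular matrix and fibrosis (camera adjusted p = 0.656; Lox, the collagen cross-linking enzyme, -0.59, adjusted p = 0.0676). Of the matrix genes 6 were lower over the list alone, with a median of 0.12 and a mean of -0.02. Pfkfb3, a regulator of glycolysis, rose by 0.51 on the log2 scale (SE 0.0788) and Gsta3, a glutathione transferase, by 0.93 (SE 0.0993), while their lists of 16 glycolysis genes and 13 NRF2 targets had a camera adjusted p of 0.887 each, with 1 glycolysis gene higher and 2 NRF2 targets higher and 2 lower over the list alone. Lists of circadian clock genes (0.121, 2 higher over the list alone; Per3, a clock gene, 0.49, adjusted p = 0.0625), hypoxia and angiogenesis genes (0.422, 4 higher and 3 lower over the list alone; Vegfa, the endothelial growth factor, 0.38, adjusted p = 0.0656) and cytosolic ribosomal proteins (0.291; Rpl10a, -1.36 from a WT mean of 0.787 CPM, adjusted p = 0.087) gave the camera adjusted p that opens each bracket. Red blood cell and skeletal muscle markers gave 0.887 and 0.934, with Hbb-bs, a haemoglobin chain, at 0.16 (adjusted p = 0.526) and Pvalb, parvalbumin, at -1.62 (adjusted p = 0.0595), the 1 muscle marker lower over the list alone, in a list with a median of 0.24 and a mean of -0.16. No member of these lists passed without WT replicate 1, Pfkfb3 and Gsta3 included (adjusted p = 0.116 and 0.0617). Without Jmjd8-KO replicate 2, 1 matrix gene rose and 6 fell, 2 progenitor markers rose and 1 fell, 3 NRF2 targets rose and 2 fell, and 3 hypoxia genes rose and 1 fell; 3 clock genes and 1 glycolysis gene rose, 1 muscle marker fell, and 0 endothelial, red blood cell or ribosomal genes passed. As lists, the circadian clock and ribosomal protein genes passed in that fit and without both libraries that stand apart. Without Jmjd8-KO replicate 2 the median was -0.27 for muscle, -0.02 for matrix, 0.09 for progenitor and 0.01 for endothelial markers, so the first 3 changed sign.

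Of the 40 lists, 36 were tested and 19 passed, 10 higher and 9 lower. With an estimated correlation between genes 0 passed (fry called 19, of which 17 were among them), and without WT replicate 1, 15 did.

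**Figure D3:**
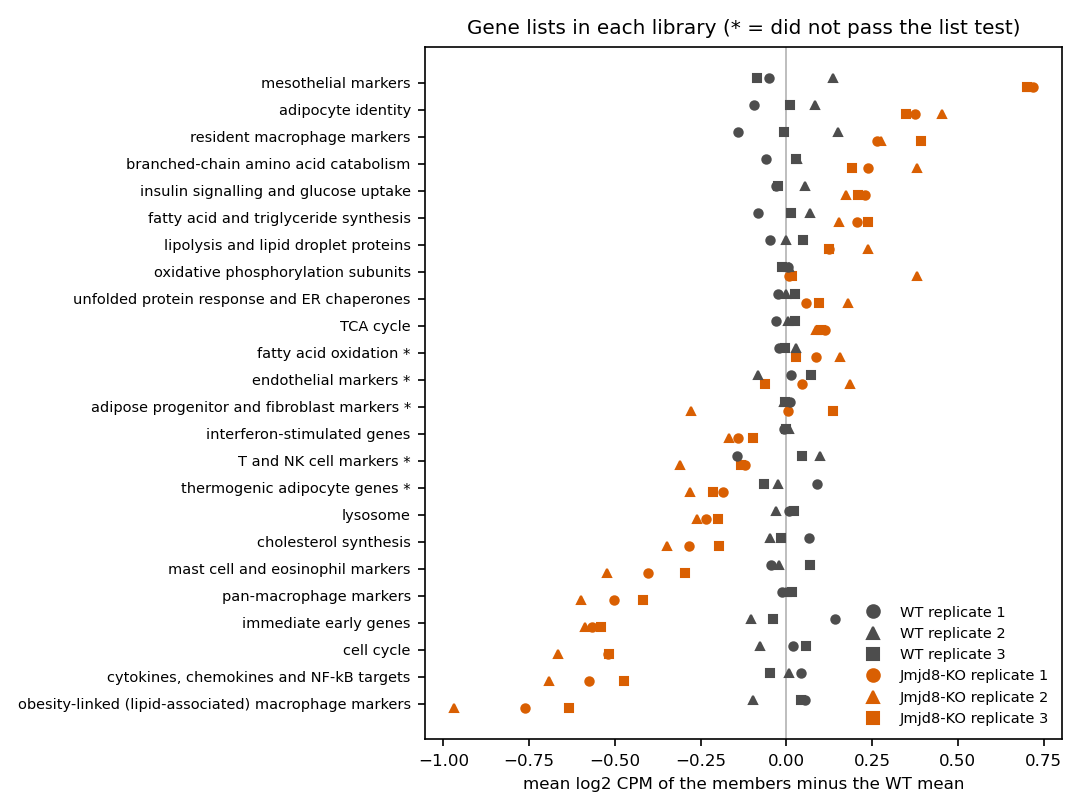
Mean log2 CPM of the members of each list in every library, minus the mean of the 3 WT libraries. Points are mice, grey for WT and orange for Jmjd8-KO, and an asterisk marks the 5 lists shown that did not pass. Scores of obesity-linked macrophage markers lay between -0.97 and -0.63 in Jmjd8-KO and between -0.10 and 0.05 in WT.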

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

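The fit without both libraries that stand apart, the GC and length offsets and the robust fit were chosen after seeing the data; the other settings were fixed before. No gene of the 304 changed sign in any of the settings, which is no test of stability, as the groups do not overlap in any of them. The causes of the changes in count were not tested except where given. The count stayed between 287 and 372 with RLE, upper-quartile or library-size scaling, limma-voom, the stricter filter, the robust fit and the GC and length offset, although library size alone called 288 lower. DESeq2 called 1039 (503 higher, 536 lower); in the simulation 23.8% of its calls were genes that had not been changed. Limma-voom with quality weights called 2030 (998 and 1032). No filter on low counts gave 156 (50 and 106) over 19120 genes, and glmTreat with a minimum log2 fold change of 0.5 gave 9 (2 and 7). Leaving out each mouse in turn gave 0 to 1351 genes, 0 to 654 higher and 0 to 697 lower, on 5 libraries each; leaving out both that stand apart gave 2833 (1444 and 1389), which include all 304. For Jmjd8 the log2 fold change was -1.47 to -1.18 without each mouse in turn, and -1.28 with glmTreat (adjusted p = 0.109). With the correlation estimated for each list 0 lists were called, and 15 to 20 in the other settings. Depth limits the genes near 1 CPM most.

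No pairing of the mice by replicate number was seen. Deviations from the group mean correlated at -0.018, -0.029 and 0.008 between mice of the same number, and at most 0.025 between others. With 3 mice per group, and a library in each that stands apart, these values cannot show or exclude a pairing. With the replicate number as a block, 5 genes were called (1 higher, 4 lower), 18 lists, and Jmjd8 had a log2 fold change of -1.30 and an adjusted p over 0.05. With the block and the GC and length offset, 138 genes were called (36 higher, 102 lower), and Jmjd8 passed.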

Other observations

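The genes in this paragraph and the next were picked after their values were seen, and all tests of explanations below were chosen after the result was seen. These picked genes form no tested group. Cd72, a receptor of B cells and macrophages, went from 23.9 ± 2.00 to 8.37 ± 1.21 CPM (log2 fold change -1.51), Lair1, an inhibitory collagen receptor, had -1.36, Ms4a7, a membrane protein of macrophages, -1.13, and the lectins Clec7a (dectin-1) and Clec12a -1.03 and -0.95. Hpgds, the haematopoietic prostaglandin D synthase, fell 2.64-fold. Mmp3 and Adam8, proteases of the matrix and the cell surface, fell 2.93- and 2.10-fold, and the transcription factors Prrx1 and Runx2 2.35- and 1.98-fold. Tph2, a tryptophan hydroxylase best known from serotonin neurons, fell from 118.4 ± 8.07 to 47.7 ± 0.914 CPM (adjusted p = 0.00288; log2 fold change -1.31 with WT replicate 1 and -1.29 without it), and Trdn, triadin of the muscle calcium release complex, had -1.48. Adjusted p for the others lay between 0.0125 and 0.0428. With WT replicate 1 left out the log2 fold change was -1.45 for Cd72 and -0.94 for Clec12a. In that fit Cd72, Ms4a7, Clec12a, Mmp3, Tph2 and Trdn passed, while Lair1, Clec7a, Hpgds, Adam8, Prrx1 and Runx2 did not.

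Among genes that rose, Car3, carbonic anhydrase 3, went from 6264 ± 1055 to 10420 ± 473 CPM (log2 fold change 0.73), Apcdd1, a Wnt inhibitor, and Fam13a rose 2.11- and 2.10-fold, Nrip1, a nuclear receptor corepressor, 1.60-fold, and Zbtb16 and Fkbp5, both targets of the glucocorticoid receptor, 1.85- and 1.52-fold. Plagl1 and Peg3, imprinted genes, had log2 fold changes of 1.03 and 0.82. Adjusted p for these 8 genes lay between 0.0156 for Apcdd1 and Fam13a and 0.0495 for Fkbp5, and none of the 8 passed without WT replicate 1 (adjusted p from 0.0504 for Apcdd1 and Fam13a to 0.158 for Fkbp5). With Nnat they were the 3 that rose of 20 imprinted genes measured, of which 10 had a positive log2 fold change (median -0.01). A list of those 20, written after these 3 were seen, did not pass (camera p = 0.878; p = 0.919 with an estimated correlation), a negative result for imprinted genes as a group.

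Capn11 and Crisp1, the former named after its values were seen, were absent from a whole group. They were the genes with 0 counts in every mouse of one group and at least 10 in every mouse of the other. Capn11, a calpain, had 12, 17 and 12 counts in Jmjd8-KO and 0 in WT, at least 13.8-fold higher if 3 counts are allowed over the WT group. Crisp1, a secreted protein of the epididymis and the 1 measured marker of epididymis and testis, had 0 counts in Jmjd8-KO and 12, 16 and 10 in WT, at least 12.5-fold lower. Both lie on chromosome 17, as does Jmjd8, Capn11 at 45630204 to 45659325 and Crisp1 at 40293758 to 40319207. Of 691 tested genes on that chromosome 20 passed (2.89%), against 2.08% elsewhere (Fisher's exact test, p = 0.173). Hspa1a, Hspa1b and H2-DMb1, which passed, also lie there, between 34153072 and 34972156. The test covers the chromosome as a whole and cannot speak to a stretch near Jmjd8, which was not tested. Neither Capn11 nor Crisp1 passed without WT replicate 1 (adjusted p = 0.0779 and 0.105). Eif2s3y, a Y-linked translation factor, fell in Jmjd8-KO (log2 fold change -0.76, adjusted p = 0.0244), and the Y-linked Ddx3y, Uty and Kdm5d had -0.51, -0.55 and -0.38, all 4 passing over the sex check list alone. Of genes also named after their values were seen, Retnlg, a neutrophil gene, had 2.05 (adjusted p = 0.0676), and Fbxl16, a neighbour of Jmjd8, had -3.16 (adjusted p = 0.256) from 73.1 CPM in WT replicate 1 against 2.33 and 2.77 CPM in the other WT mice (0.18 without WT replicate 1). Between the groups neuron markers had a camera p of 0.0416 (p = 0.464 with an estimated correlation) and microglia markers of 0.218 (p = 0.277 with an estimated correlation), with 0 members of either called by edgeR.

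WT replicate 1 held nervous-system transcripts. Over 36 markers of neurons, oligodendrocytes, astrocytes and choroid plexus, its median log2 excess over the other WT mice was 5.58, with 35 above 0 (medians by list 5.96, 5.50, 2.80 and 1.96), while microglia markers, shared with fat macrophages, had 0.15. Peripheral nerve in the fat pad was argued against, as its markers had a median of 0.52 and 4 of 5 lay below the lower quartile of the brain markers, 3.21. Genomic DNA or a raised background was argued against by liver, kidney and heart markers, with a median of -0.20 and 11 of 11 below that quartile (medians by list -0.20, -0.32 and -0.07). Brain RNA in this library is therefore the explanation left of those tested, and how it got there was not tested. Xist had 193 counts in it, against 0 to 2 elsewhere, beside the Y-linked genes. The excess of the 923 genes over 4-fold above every other library makes up 1.2% of the counts of WT replicate 1. That share leaves out brain RNA in genes that fat also expresses, so it is not the full amount.

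Jmjd8-KO replicate 2 differed from Jmjd8-KO replicates 1 and 3 over 10015 genes of at least moderate level. The SD of its deviation was 0.401 against 0.123 between the other 2, and it followed GC content (Spearman rho 0.36) and length (-0.27). A trend with both as the whole cause was argued against, since removing it took away 17.9% of the variance and left an SD of 0.364 against 0.114. Another makeup of cell types as the whole cause was argued against too, since markers of a cell type spread as widely as all genes (ratio of SDs 1.03, median of 6 lists). RNA quality, the library preparation and a difference of this mouse itself were not tested and stay open.

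Lower macrophage and cytokine genes with higher adipocyte genes were weighed against 3 explanations. A larger share of adipocyte RNA, as the only change, would lower the markers of every other cell type alike. Endothelial and progenitor markers less macrophage and cytokine genes scored 0.61 higher in Jmjd8-KO (SD 0.07 in Jmjd8-KO and 0.033 in WT), which argues against it as the only change. The score sets lists already seen not to pass against genes already seen to fall, so it is no independent test. A larger adipocyte share together with a separate change in macrophages is not excluded. The libraries that stand apart were argued against as the source for the 50 macrophage and cytokine genes, since without both their median was -0.55 against -0.63. The median of adipocyte identity genes shrank more, to 0.28 from 0.39. No verdict was set for those genes, so a part played by these libraries is not excluded there. Fewer macrophages of every kind, as the only change, would lower resident markers as well. Resident markers less pan-macrophage markers scored 0.82 higher (SD 0.055 and 0.14), which argues against it as the only change. The 2 lists had already been seen to rank in opposite directions, so the score is no independent test. Of 10 resident markers 3 rose and 7 did not pass, so a loss of macrophages together with a rise of a few genes is not excluded. A lower share of recruited macrophages, or lower expression of these genes per macrophage, in Jmjd8-KO fat stays open as a hypothesis that these data did not test.

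The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. The real split, 1 of 10, called 304 genes and the highest other 0. For lists the real split, again 1 of 10, called 19 and the others 0 to 13. Each other split mixes the genotypes, so a genotype difference would widen the spread within its groups and lower its calls of genes. The 0 is therefore no measure of how many genes would be called by chance.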
